A study of Mus musculus with 6 samples.

How the data were processed

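RNA of sorted mouse regulatory T cells was measured on 6 Affymetrix mouse genome arrays, 3 pools of nTreg and 3 of iTreg. Per the labels' protocols, the recipients were pups of Foxp3-deficient litters injected into the peritoneal cavity within 30 hours of birth, and cells were sorted at 50 days of age. The labels give a mean purity of 98.8% ± 0.2 and a viability of 87.6% ± 1.6 for sorted CD4 populations (n = 23), without tying these figures to the 6 pools. RNA was extracted with Trizol and labelled from 6 µg, per the labels. The values used are the log2 signals of 45101 probe sets that the authors deposited. That they are on a log2 scale was read from their range, and the software that summarised and normalized them is not given in the sources used here. Array medians differed by at most 0.14, and no further normalization was applied.

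Probe sets were named from the platform annotation of the arrays, with current symbols from a mouse gene table (assembly GRCm38.p6, used for names only). Of 45037 probe sets other than the 64 Affymetrix controls, 34945 had 1 gene, 932 several and 9160 none. Probe sets with several genes or none were not named. Those with a mean below the 40th percentile of the non-control probe sets (log2 5.01) were left out, which left 27022 and removed 18015. A gene was represented by its tested probe set with the highest mean over the 6 arrays, and 5653 of the 12691 genes had more than 1 tested probe set.

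The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all tested probe sets, threshold 0.05), on all 6 arrays and without covariates. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 33 lists, and again with the correlation estimated per list and with fry. Camera sets a list against the other genes, so its direction can differ from the sign of the list's mean. Controls were compared with exact permutation tests. The labels describe the samples as replicate pools but do not say whether pools came from separate mice, so p-values measure the spread between these pools only.

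The labels give the numbers 1 to 3 to both groups. Whether the numbers pair the arrays was checked from the values, as the labels name no shared litter or day. The deviations from the group means of same-numbered arrays correlated at 0.50, 0.70 and 0.62 across genes, all above 0.1, while those of differently numbered arrays lay between -0.53 and -0.15. Deviations within a group cancel out for each gene, so positive values at the same number make the others negative on average. Only the positive values at the same number therefore count as evidence. The numbers were therefore taken to pair the arrays, and a fit with the replicate number as a block was set beside the fit without it. That fit called 0 probe sets as well.

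The lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined, except where stated. The rule names Foxp3, the 5 origin markers and up to 12 genes in each direction past the threshold whose groups lie apart. If fewer than 10 pass, it gives the 10 with the smallest p in each direction instead, and this applied. For lists it names up to 4 members past the threshold. Since none passed, the members with the largest differences in the direction of the list are given, with some members that differed the other way, and these were chosen after their values were seen. Listed genes without a match among the named probe sets were not analysed here. Older gene names were matched through the synonyms of the gene table, but never where the listed name is itself a current symbol.

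The fits were tested on simulated data with 27022 probe sets, of which 200 were changed, 100 for each size, in 5 draws. With effects shared by arrays of the same number, the fit without a block recovered 0% of changes of 1 on the log2 scale and 26% of changes of 2. The fit with the block recovered 66.6% and 99.8%, with an average of 15.4 false calls. The simulated spread of a gene was equal at all numbers, and genes were drawn independently. In these data the SD of the differences across genes was 0.57 at number 1, and 0.33 and 0.29 at numbers 2 and 3. The simulated recovery therefore need not hold here. With spread between arrays only, the fit without a block recovered 2.8% and 75.6%, with 5.6 false calls, and the fit with the block 0% and 22%, with 2.4. In simulated lists of 20 genes camera called 100% of 50 lists shifted by 0.5 and 2% of unchanged ones. Calls there used an unadjusted p under 0.05, and genes were drawn independently, without effects shared by arrays of the same number. These rates therefore do not carry over to lists whose genes move together. In these data the estimated correlation between genes was 0.66 for the Treg core list and 0.050 for the cell cycle list.

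The alternatives were quantile normalization, centring of arrays on their medians, no filter on dim probe sets, a filter at the 60th percentile, a trended and robust prior, the replicate block, array weights, the mean of all probe sets of a gene, an adjusted p of 0.01 and the omission of each array in turn. Added after the data were seen were a fit without the arrays numbered 1 in both groups, and the replicate block with an estimated correlation.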

Results

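Gene expression was measured in regulatory T cells, the CD4 T cells that restrain immune responses under the control of the transcription factor Foxp3. The 6 arrays held 3 pools of natural regulatory T cells (nTreg) and 3 pools of regulatory T cells induced in the animal (iTreg). Each pool came from 4 to 8 treated mice aged 50 days, on the BALB/c background and deficient in Foxp3 because of the K276X mutation. These mice were recipients of a transfer into the peritoneal cavity within 30 hours of birth. The cells were positive for EGFP and Thy1.1 and were sorted from spleen and lymph nodes. Values were given for 45101 probe sets, between 2.57 and 14.8 on the log2 scale, and the medians of the 6 arrays lay between 5.51 and 5.65. The number of arrays, 3 per group, limits the precision of every comparison. The comparison of iTreg with nTreg asks how expression differs between cells induced in the animal and cells of natural origin. Naive conventional T cells and cells induced in culture, which the series design also mentions, were not analysed here.

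No single gene passed the test between iTreg and nTreg, and the differences that passed lay in groups of genes. Cell cycle genes averaged lower in iTreg, by a log2 difference of -0.22, and genes of the heat shock and unfolded protein response averaged higher, by 0.24. Both differences had the same sign at each of the 3 replicate numbers and passed camera's test whichever array was left out. Genes of the regulatory T cell signature averaged 0.51 higher in iTreg, and markers of CD8 T and NK cells averaged lower, at -0.41. Both of these rested on nTreg replicate 1, without which they were -0.081 and 0.23. Markers of monocytes, macrophages and granulocytes averaged -0.59, or -0.18 without iTreg replicate 2, where their call ended. These calls used camera with a preset correlation between genes, and none of them passed when the correlation was estimated from the 6 arrays. Splits of the arrays that mixed the groups gave up to 18 passing lists, against 11 in the real split.

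Both groups were sorted on EGFP, which reports Foxp3 in the strains named in the labels, so Foxp3 was examined first on each array. The 1 probe set annotated to it was dim on all 6 arrays. The nTreg arrays read 4.69, 4.33 and 4.07 (mean 4.36 ± 0.31 SD, n = 3) and the iTreg arrays 4.72, 4.47 and 4.42 (4.54 ± 0.16 SD, n = 3). The difference was 0.17 (SE 0.19), or 0.029 without nTreg replicate 3, 0.084 without iTreg replicate 1 and 0.34 without nTreg replicate 1. Its mean lay at the 28.2th percentile of all non-control probe sets, below the limit for testing, so a difference in Foxp3 was not detectable at this signal.

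Genes used elsewhere to tell thymic from induced regulatory T cells overlapped between the groups. Ikzf2, which encodes the transcription factor Helios, read 12.16 ± 1.12 in nTreg and 12.52 ± 0.47 in iTreg (mean ± SD, n = 3 each), and all 3 of its tested probe sets read higher in iTreg. Nrp1, the surface receptor neuropilin-1, read 11.04 ± 1.10 in nTreg and 11.39 ± 0.86 in iTreg, with 3 of its 4 tested probe sets higher in iTreg. Swap70 read 10.71 ± 0.30 in nTreg and 10.69 ± 0.68 in iTreg. Dapl1 read 6.70 ± 1.99 in nTreg and 6.26 ± 0.89 in iTreg. Igfbp4, an insulin-like growth factor binding protein, read 10.45 ± 1.44 in nTreg and 10.42 ± 1.43 in iTreg, and its 6 tested probe sets ranged from -0.38 to 0.55. None of the 5 genes passed limma's test (adjusted p = 1 for each). As a list the 5 genes had a mean difference of 0.047 and a median of -0.017, of opposite sign (camera adjusted p = 0.789). All 5 signs turned when single arrays were left out: without nTreg replicate 1, Ikzf2 stood at -0.25 and Dapl1 at 0.71.

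**Figure D1:**
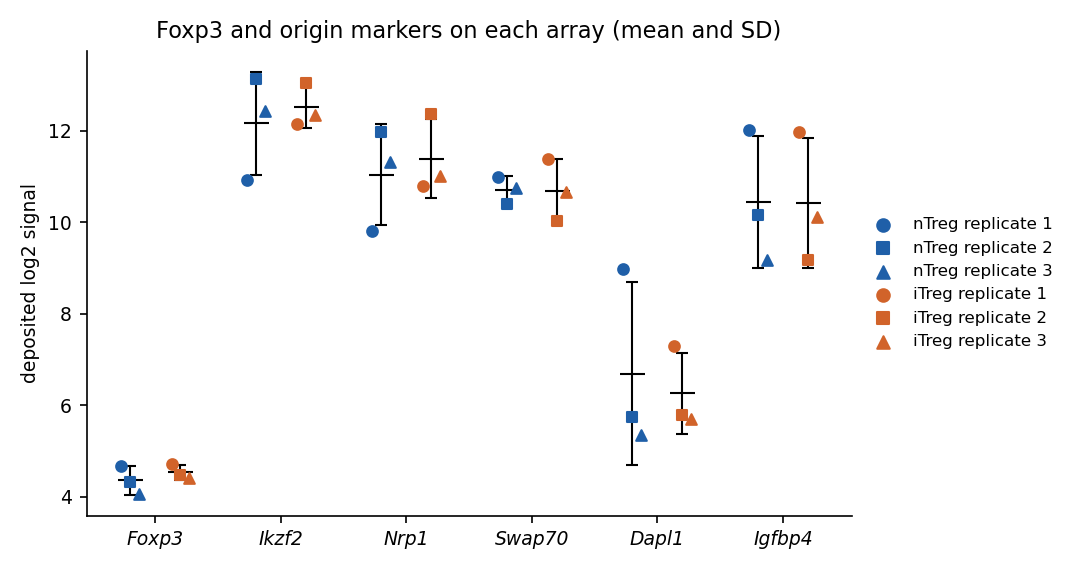
Deposited log2 signal of Foxp3 and the 5 origin markers on each of the 6 arrays (vertical axis), with the mean and SD of each group of 3. Foxp3 lay between 4.07 and 4.72 on every array, and for each origin marker the values of nTreg and iTreg overlapped.

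Among 27022 tested probe sets, 0 passed an adjusted p of 0.05 in limma's moderated test, and likewise 0 of 12691 genes (smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 45 probe sets, 21 higher and 24 lower in iTreg, where 1351 would be expected from equal groups. With the replicate number as a block, 0 passed as well, and 390 lay under an unadjusted 0.05, of which 157 were higher and 233 lower. A mean difference of at least 2-fold was reached by 58 probe sets, 25 higher and 33 lower in iTreg, and none of them passed the test. The number of 2-fold differences was 100 to 353 with any single array left out, lowest without nTreg replicate 1 and highest without nTreg replicate 3. The balance of directions moved with the arrays used: 79 were higher and 21 lower without nTreg replicate 1, 74 and 222 without iTreg replicate 1, and 72 and 8 with array weights. The 95% interval of a difference reached, at the median, 0.64 on the log2 scale to either side in the fit without a block. With the replicate number as a block it reached 0.46. All 3 values of one group lay above all 3 of the other for 543 probe sets, 2.01% of those tested, where chance alone gives 10%. That share and the 1351 expected hold for arrays that are not paired, and are too high where arrays share effects by replicate number.

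Because no gene passed, the 10 genes with the smallest p in each direction are given as values that did not pass (adjusted p = 1 for each in limma). Their choice and their SEs come from the fit without a block. Higher in iTreg was Hspb1, a small heat shock protein, which read 6.54 ± 0.16 in nTreg and 7.23 ± 0.21 in iTreg (log2 difference 0.69, SE 0.21). Il17rb, a subunit of the interleukin 25 receptor, differed by 0.63 (SE 0.24), and Gpr183, an oxysterol receptor that positions lymphocytes, by 0.57 (SE 0.22). Postn, which encodes the matrix protein periostin, differed by 0.99 (SE 0.34; 0.65 without iTreg replicate 3), Laptm4b, a lysosomal membrane protein, by 0.53 (SE 0.20), and Emd, the nuclear membrane protein emerin, by 0.71 (SE 0.28). Nckap5, Prcc, Gpm6b and Syt17 completed the list, at 1.13, 0.64, 0.71 and 0.59. For Gpm6b and Syt17 another tested probe set of the gene lay on the other side of 0, at -0.069 and -0.057.

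Lower in iTreg was C1qb, a chain of complement C1q, which read 8.15 ± 1.24 in nTreg and 6.32 ± 0.22 in iTreg, a difference of -1.84 (SE 0.57) with all 3 tested probe sets lower. C1qa, another chain, differed by -1.35 (SE 0.52). Without nTreg replicate 1 these genes differed by -1.14 and -0.73. The lectin receptors Clec4n and Mrc1 differed by -1.23 (SE 0.38) and -1.29 (SE 0.51), and the iron exporter Slc40a1 and the haem oxygenase Hmox1 by -0.95 (SE 0.37; -0.61 without iTreg replicate 2) and -0.57 (SE 0.21). Lpl, lipoprotein lipase, read 7.12 ± 0.28 in nTreg and 5.90 ± 0.59 in iTreg, a difference of -1.23 (SE 0.33). The adhesion molecule Vcam1 differed by -1.08 (SE 0.39) and the collagen gene Col14a1 by -0.67 (SE 0.26). E2f2, a transcription factor of the cell cycle, differed by -0.51 (SE 0.19). The 3 values of each group were fully apart for 17 of the 20 genes, and overlapped for Emd, Vcam1 and Mrc1. Over all tested probe sets this share was 2.01%. Choosing genes by the smallest p on the same arrays favours such separation, so the count is no support for them.

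**Figure D2:**
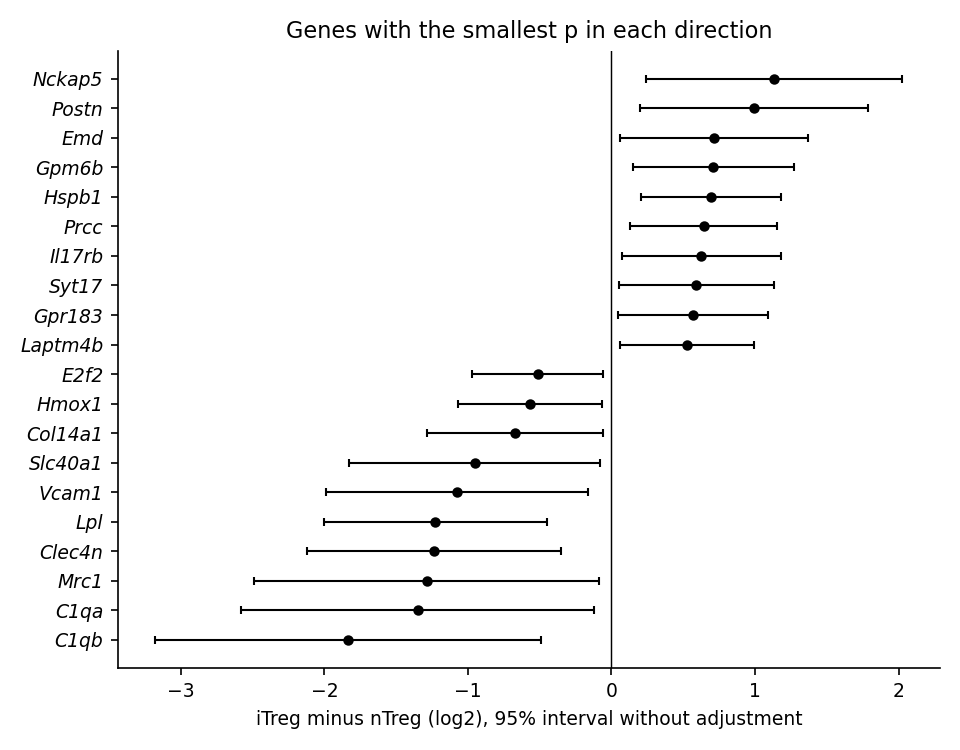
Log2 difference, iTreg minus nTreg (horizontal axis), of the 10 genes with the smallest p in each direction, with the 95% interval of each difference without adjustment for the number of tests. The intervals come from the fit without a block. Differences ran from -1.84 for C1qb to 1.13 for Nckap5, and no gene passed after adjustment.

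In camera's test 11 of 33 gene lists passed an adjusted p of 0.05, 8 higher and 3 lower in iTreg. Of the 10 splits of the arrays into 3 against 3, 6 gave at least as many lists, the real one included. With the replicate number as a block the count was 17, with the correlation estimated per list it was 0, and fry, which tests whether a list moves one way, called 0. With array weights the count was 4, of which 3 were among the 11 and the interferon list was the other. It was 20 without nTreg replicate 2, 17 without iTreg replicate 1 and 7 without iTreg replicate 2. Without replicate 1 in both groups, a setting chosen after seeing the data, it was 6, of which 3 were among the 11. No member of any list passed limma's test, over all probe sets or adjusted over the list alone (0 genes in both). With the replicate block 4 passed adjusted over the list alone, Hspa1a and Hspa1b in the heat shock list and Eif2s3y and Kdm5d in the sex-linked list.

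The cell cycle list was lower in iTreg for 39 of 42 tested genes, with a mean difference of -0.22 and a median of -0.20 (camera adjusted p = 1.0e-14; adjusted p = 0.168 with an estimated correlation). The largest differences were those of Ccnb2, cyclin B2, at -0.64 (SE 0.39), of the spindle protein Tpx2 at -0.54 (SE 0.23) and of the mitotic kinase Aurkb at -0.53 (SE 0.24). Ccna2, cyclin A2, differed by -0.47. Cdc45, Pcna and Rrm1 were the 3 genes higher in iTreg, at 0.28, 0.25 and 0.14. The list's difference was -0.22, -0.21 and -0.23 between the arrays numbered 1, 2 and 3, and between -0.27 and -0.16 with single arrays left out. Over 18 alternatives the adjusted p ran from 7.4e-16 to 0.929. Beside this, erythroid markers, which belong to another dividing cell type, differed by 0.23, -1.33 and 0.068 between the same arrays.

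The heat shock and unfolded protein response list was higher in iTreg for 19 of 22 tested genes, with a mean difference of 0.24 (camera adjusted p = 5.6e-05; adjusted p = 0.312 with an estimated correlation). The inducible chaperone genes Hspa1a and Hspa1b differed by 1.15 (SE 0.81) and 0.79 (SE 0.56), Hsph1 by 0.51 (SE 0.33) and Dnaja1 by 0.39 (SE 0.28). With the replicate block Hspa1a (SE 0.18) and Hspa1b (SE 0.18) passed limma's test adjusted over the list alone (adjusted p = 0.0115 and 0.0407), and both were higher in iTreg at each replicate number, by 0.56 to 1.33. The list's difference was 0.20, 0.19 and 0.32 between the arrays numbered 1, 2 and 3, and over 18 alternatives the adjusted p ran from 7.3e-06 to 0.929. Members of the endoplasmic reticulum lay on both sides of 0, among them Pdia4 at 0.32 and Hsp90b1 at 0.25. The 3 members below 0 were Calr, Creld2 and Herpud1, at -0.082, -0.074 and -0.0046.

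The Treg core list was higher in iTreg for 25 of 28 tested genes, with a mean difference of 0.51 (camera adjusted p = 2.4e-08; adjusted p = 0.585 with an estimated correlation). Klrg1, a receptor of differentiated effector cells, differed by 1.19 (SE 0.60), the cytokine gene Il10 by 1.11 (SE 0.45), Tnfrsf9 by 0.93 (SE 0.85) and the interleukin 2 receptor chain Il2ra by 0.93 (SE 1.01). The list's difference was 1.38 between the arrays numbered 1, and -0.0046 and 0.14 between those numbered 2 and 3. Without nTreg replicate 1 the difference was -0.081 (camera adjusted p = 0.121), so the call rested on that array, and without nTreg replicate 2 it was 0.91. It was 0.070 without replicate 1 in both groups, where the call also ended. Over 18 alternatives the adjusted p ran from 2.8e-14 to 0.929. On nTreg replicate 1 Il2ra read 7.03, against 10.25 to 11.24 on the other 5 arrays. The same array had the highest scores for markers of B cells, MHC class II and CD8 T and NK cells, at 2.78, 2.03 and 1.5 above each list's mean over the 6 arrays. On iTreg replicate 1 these lists scored 1.82, 1.61 and 0.25, while the Treg core list stood at -0.048.

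Another 6 lists were also higher in iTreg by camera's test. Coinhibitory and costimulatory receptors had 17 of 23 genes higher and a mean of 0.23 (adjusted p = 0.0106; adjusted p = 0.585 with an estimated correlation), led by Tnfrsf9, Tnfrsf18 at 0.81 and the inhibitory receptor Ctla4 at 0.75, with Cd244a at the other end, at -0.88. The IL-2 and STAT5 pathway had 15 of 18 genes higher and a mean of 0.29 (adjusted p = 0.0018; adjusted p = 0.585 with an estimated correlation), led by Il2ra, Socs2 at 0.77 and Pim1 at 0.70. The effector and memory list had 18 of 26 genes higher and a mean of 0.21 (adjusted p = 0.0166; adjusted p = 0.632 with an estimated correlation), led by Klrg1, Il10 and Tnfrsf9, with Lgals3 at the other end, at -0.53. The Th2 list, of which only 6 of 15 fixed genes were tested, had all 6 higher and a mean of 0.33 (adjusted p = 0.0012; adjusted p = 0.585 with an estimated correlation). Among them were the chemokine receptor genes Ccr4 at 0.46 and Ccr8 at 0.43 and the transcription factor Gata3 at 0.39. The Th2 difference was 0.70, -0.022 and 0.31 between the arrays numbered 1, 2 and 3. Chemokine receptors and integrins had 16 of 23 genes higher and a mean of 0.19 (adjusted p = 0.0319; adjusted p = 0.585 with an estimated correlation), led by the gut homing receptor Ccr9 at 0.89, Gpr15 at 0.89 and the integrin chain Itgae at 0.83. The T cell receptor early response list had 21 of 31 genes higher and a mean of 0.15 (adjusted p = 0.0025; adjusted p = 0.632 with an estimated correlation), led by Pim1, Jun at 0.55 and Dusp5 at 0.49. Over 18 alternatives the smallest adjusted p was 9.4e-05, 3.6e-07, 4.5e-04, 3.6e-05, 0.0049 and 1.1e-08 in the order given, and the largest 0.929, or 0.972 for the effector list.

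These lists share members: 17 of the 28 tested Treg core genes, 13 of the 26 effector genes and 10 of the 18 IL-2 pathway genes stand in another list. Without nTreg replicate 1, on which the Treg core list was lowest and the B cell, MHC class II and CD8 T and NK cell lists were highest, camera's calls ended for coinhibitory receptors at -0.028, the IL-2 pathway at -0.024, the effector list at 0.021, Th2 at 0.075 and chemokine receptors at 0.084. Without iTreg replicate 2 they ended for coinhibitory receptors at 0.14, the effector list at 0.086, the IL-2 pathway at 0.22 and Th2 at 0.26. Without iTreg replicate 1 they ended for T cell receptor early response at -0.044 and chemokine receptors at 0.21, and without nTreg replicate 3 for T cell receptor early response at 0.031. Without iTreg replicate 3 they ended for coinhibitory receptors at 0.25 and chemokine receptors at 0.15, and T cell receptor early response was 0.36. Without nTreg replicate 2 the means were larger, at 0.41 for coinhibitory receptors, 0.58 for the IL-2 pathway, 0.41 for the effector list, 0.57 for Th2, 0.29 for chemokine receptors and 0.24 for T cell receptor early response.

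Other settings ended calls among these 6 lists as well. Quantile normalization ended those of the effector list, at 0.19, and of chemokine receptors, at 0.18. Without a filter on dim probe sets the same 2 lists, at 0.21 and 0.18, and Th2, at 0.12, did not pass. With array weights none of the 6 passed, at 0.079 for coinhibitory receptors, 0.043 for the IL-2 pathway, 0.013 for the effector list, 0.16 for Th2, 0.16 for chemokine receptors and -0.010 for T cell receptor early response. Without replicate 1 in both groups none passed either, at 0.045, -0.012, 0.080, 0.14, 0.097 and -0.018 in the same order.

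**Figure D3:**
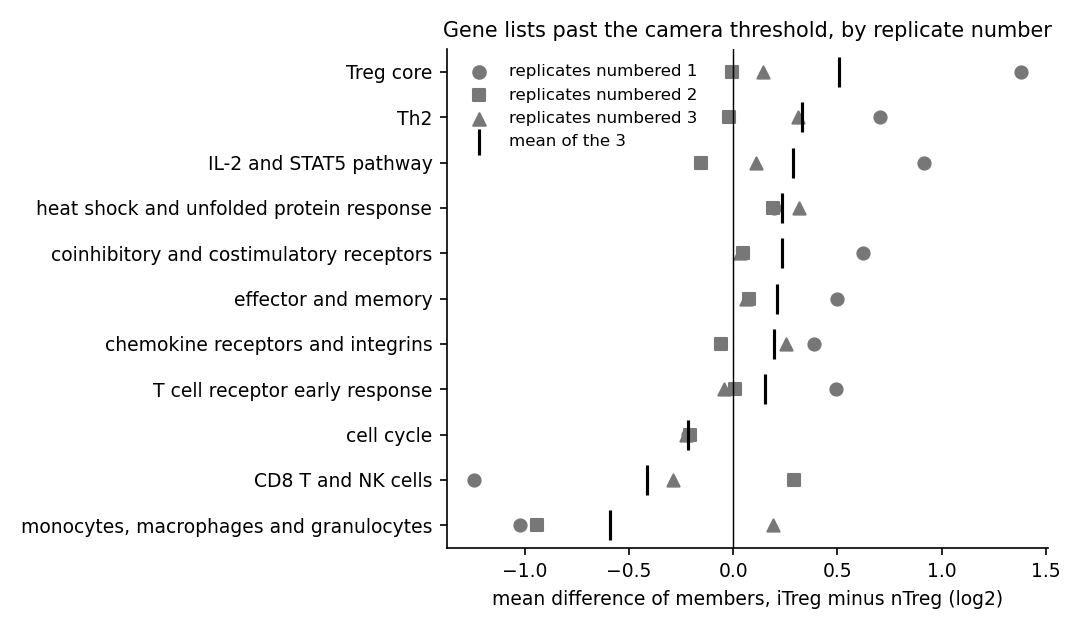
Mean log2 difference, iTreg minus nTreg, of the members of the 11 lists past camera's threshold (horizontal axis), between the arrays that share a replicate number (circles 1, squares 2, triangles 3) and as the mean of the 3 (bars). The cell cycle list lay between -0.23 and -0.21 and the heat shock list between 0.19 and 0.32, while the Treg core list ran from -0.0046 to 1.38.

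Markers of monocytes, macrophages and granulocytes were lower in iTreg for 24 of 27 tested genes, with a mean difference of -0.59 (camera adjusted p = 2.5e-11; adjusted p = 0.585 with an estimated correlation). Besides C1qb and C1qa, Adgre1, the macrophage antigen F4/80, differed by -1.10 (SE 0.51). The list's difference was -1.02 and -0.94 between the arrays numbered 1 and 2, and 0.19 between those numbered 3. At number 3 the list was mixed, with 11 of 27 genes lower in iTreg. There C1qb read 7.71 in nTreg and 6.09 in iTreg, and Adgre1 7.11 and 6.5. The granulocyte genes Ngp, at 11.41 and 12.5, and S100a9, at 8.92 and 10.27, went the other way. C1qb, C1qa and Adgre1 were lower in iTreg at each number. Without iTreg replicate 2 it was -0.18 and the call ended (camera adjusted p = 0.569), without nTreg replicate 1 it was -0.27 and without iTreg replicate 3 it was -0.90. With array weights it was -0.15 and the call ended, and without replicate 1 in both groups it was -0.38. Over 18 alternatives the adjusted p ran from 8.4e-25 to 0.929.

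Markers of CD8 T and NK cells were lower in iTreg for all 14 tested genes, with a mean of -0.41 (camera adjusted p = 6.4e-05; adjusted p = 0.585 with an estimated correlation). Klrd1 differed by -1.07 (SE 1.14), Ncr1 by -0.83 (SE 0.65), Fcgr3 by -0.75 (SE 0.53) and Cd8a by -0.57 (SE 0.40). The list's difference was -1.24, 0.29 and -0.29 between the arrays numbered 1, 2 and 3, and without nTreg replicate 1 it was 0.23 and the call ended (camera adjusted p = 0.0927). The call also ended with array weights, at -0.29, and without replicate 1 in both groups, at 0.00061. The difference was -0.77 without nTreg replicate 2, -0.70 without nTreg replicate 3, -0.64 without iTreg replicate 1 and -0.19 without iTreg replicate 3. Over 18 alternatives the adjusted p ran from 1.3e-09 to 0.929.

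**Figure D4:**
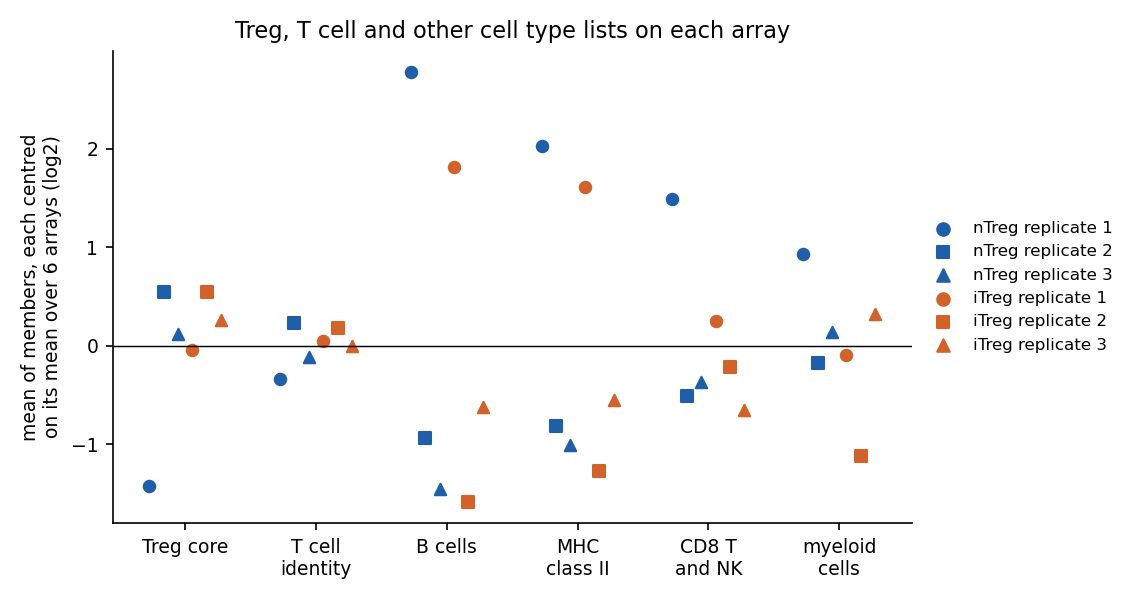
Mean of list members on each array, each gene centred on its mean over the 6 arrays (vertical axis, log2), for regulatory T cell, T cell identity and other cell type lists. On nTreg replicate 1 the Treg core list stood at -1.43 and the B cell list at 2.78, the lowest and highest values plotted for those lists.

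The other 22 lists did not pass in camera's test. B cell markers were lower for all 18 genes, with a mean of -0.26 (adjusted p = 0.151; adjusted p = 0.0021 with the replicate block), although the difference was 0.83 between the arrays numbered 3. TGF-beta pathway genes had a mean of 0.21 (adjusted p = 0.0692; adjusted p = 0.0094 with the replicate block), dendritic cell markers -0.14 (0.183; 0.0218 with the block), erythroid markers -0.35 (0.0778; 0.0494 with the block), conventional T cell identity genes 0.15 (0.0618; 0.0494 with the block) and sex-linked genes -0.38 (0.195; 0.0032 with the block). The sex-linked list joins Xist, at 2.15, with Y-linked genes at -1.72 for Eif2s3y, -1.72 for Kdm5d and -0.25 for Uty, so its mean gives no direction for the set. With the block and an estimated correlation none of these 6 lists passed (adjusted p = 0.579, 0.561, 0.561, 0.568, 0.568 and 0.561 in the order given). Over the alternatives the smallest adjusted p of these 6 lists was 8.4e-11, 4.5e-04, 0.0021, 3.9e-07, 0.0039 and 6.2e-04 in the order given, and the largest lay between 0.929 and 0.972. T helper lists had means of -0.053 for Th1 (adjusted p = 0.382, with a median of 0.042, of opposite sign), 0.14 for Th17 (0.161) and 0.14 for Tfh (0.183). Genes of naive cells and lymph node homing had a mean of -0.051 (0.587), and interferon response genes one of -0.047 (0.161). Among metabolic lists the means were 0.058 for glycolysis (0.222), 0.045 for oxidative phosphorylation (0.354) and 0.041 for cholesterol synthesis (0.655). Apoptosis genes had a mean of 0.050 (0.661) and antigen receptor recombination genes one of 0.056 (0.847). Of the remaining cell type markers, plasma cells had a mean of 0.038 (0.655), MHC class II of -0.14 (0.354), gamma delta T cells of -0.24 (0.0907), platelets of -0.18 (0.0692) and stroma and endothelium of -0.085 (0.636).

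Some of these lists passed under other settings. Platelet markers passed in 7 of 18 alternatives, among them no filter on dim probe sets (-0.33, adjusted p = 4.4e-04), centring of arrays (-0.20, adjusted p = 0.0496) and the omission of replicate 1 in both groups (-0.47, adjusted p = 8.5e-05), over a range of 8.5e-05 to 0.934. Interferon response genes passed in 3, with array weights (-0.21, adjusted p = 0.0050), without nTreg replicate 1 (-0.23, adjusted p = 3.7e-09) and without replicate 1 in both groups (-0.16, adjusted p = 1.1e-05), over a range of 3.7e-09 to 0.986. The MHC class II list passed in 3 alternatives, oxidative phosphorylation and gamma delta T cells in 2 each, and naive cells, Th17, apoptosis and stroma in 1 each.

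The arrays numbered 2 and those numbered 3 resembled each other more than arrays of the same group, while iTreg replicate 1 correlated more with iTreg replicate 3 (0.963) than with nTreg replicate 1 (0.957). Over the tested probe sets, the correlation between the nTreg and the iTreg array of the same number was between 0.957 and 0.988 (median 0.987), and that between arrays of the same group between 0.913 and 0.963 (median 0.938). These are correlations across genes, which are not independent replicates. Of the variance across the 6 arrays, 74.0% lay between replicate numbers, 6.59% between the groups and 19.5% in the rest. The differences between iTreg and nTreg of the 3 replicate numbers did not go together across genes (r = -0.097, -0.20 and -0.098). At least 2-fold differences numbered 2137 probe sets between the arrays numbered 1, 238 between those numbered 2 and 193 between those numbered 3.

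**Figure D5:**
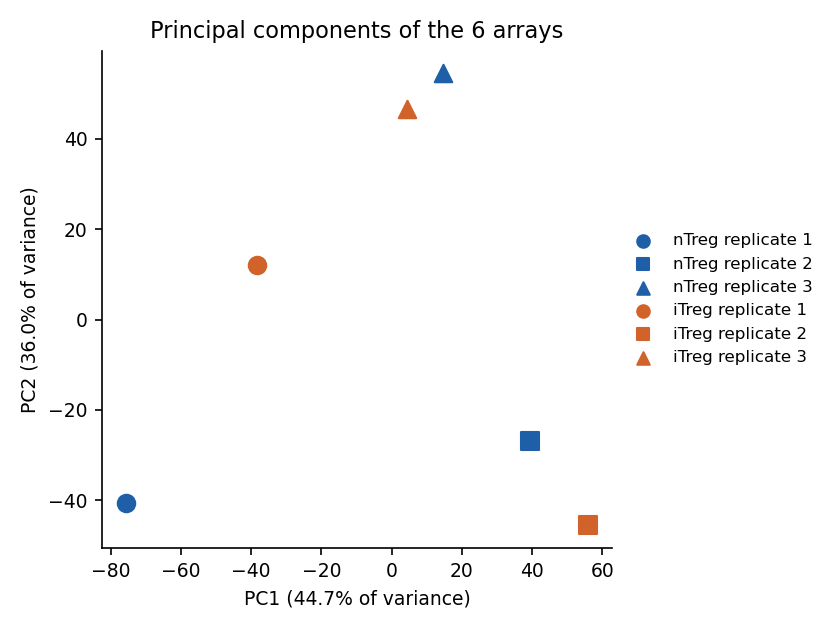
First and second principal components of the 6 arrays (axes, with their share of the variance: 44.7% and 36.0%) over the tested probe sets. The arrays numbered 2 and those numbered 3 lay close together across groups, while the nTreg and iTreg arrays numbered 1 lay apart from the others and from each other.

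Control probe sets overlapped between the groups, and the number of arrays is too small for a test of them to pass: 0.1 is the smallest p that an exact two-sided permutation test of 3 arrays against 3 allows. The 3' to 5' difference of Actb gave an exact p = 1, that of Gapdh p = 0.8 and the 18S ribosomal RNA signal p = 0.9. The 18S signal lay between 8.68 and 12.2 and was highest on nTreg replicate 1. The Actb difference was 1.57 ± 0.63 in nTreg and 1.70 ± 1.03 in iTreg (mean ± SD, n = 3), and it was largest in the arrays numbered 2, at 2.29 and 2.89. The Gapdh difference was larger, at 2.88 ± 0.68 in nTreg and 3.06 ± 0.50 in iTreg, and lay between 2.26 and 3.61. The p-values compare the groups and do not measure RNA quality. Hybridisation controls lay between 10.1 and 10.9 on all arrays.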

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

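All tests of explanations in this part were chosen after the results were seen.

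Poly-A spike-in controls (dap, lys, phe and thr), which are outside the genes tested, gave a signal above the trp control, taken as the level without an added target, which lay between 3.29 and 3.46. They stood at 13.6, 6.12 and 5.11 on nTreg replicates 1, 2 and 3, and at 9.61, 6.35 and 5.61 on iTreg replicates 1, 2 and 3. The means of 8.28 ± 4.64 and 7.19 ± 2.13 (SD, n = 3) came from values that overlapped (exact permutation p = 0.9, where 0.1 is the smallest possible), and the labels do not mention spike-in amounts.

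Cell cycle genes averaged -0.22 in iTreg against nTreg, and -0.22 ± 0.064, -0.21 ± 0.041 and -0.23 ± 0.035 (SE over genes) between the arrays numbered 1, 2 and 3. A trend with signal level left by the normalization is argued against by the list's median of -0.20, which lay below all 10000 random lists of matched mean level (-0.11 to 0.14). Dividing erythroid precursors in the nTreg pools, which the gate on CD4, EGFP and Thy1.1 should remove, could contribute and stay open: their 8 markers, none of them in another list, differed by -1.33 ± 0.41 at number 2, and by 0.23 ± 0.30 and 0.068 ± 0.17 at numbers 1 and 3, which within 2 SE still allows a fall as large as that of the cell cycle genes. At number 1 the markers went both ways, with 3 of 8 lower in iTreg (the abundant Car2 at 9.95 in nTreg and 8.92 in iTreg, and Bpgm at 8.04 and 9.18). Dividing B or myeloid cells should also be removed by the gate. At number 3 B cell markers were higher in iTreg by 0.83 ± 0.094 (Ighm at 12.67 in nTreg and 13.28 in iTreg). Myeloid markers were higher there by 0.19 ± 0.14, while cell cycle genes stood at -0.23. On nTreg replicates 1 and 2 B cell markers scored 2.78 and -0.935, and the cell cycle list 0.166 and 0.158. On iTreg replicates 1 and 2 these scores were 1.82 and -1.585, and -0.053 and -0.049. Erythroid markers scored 0.81 and -0.997 on those iTreg arrays. These scores argue against B cells as the whole cause. On nTreg replicate 3 both lists were lowest of the nTreg arrays, so a contribution of these cells stays open. An untested difference in division between cells of natural and induced origin stays open too.

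On nTreg replicate 1 the Treg core genes were lower than on nTreg replicates 2 and 3, by a mean log2 difference of -1.76 ± 0.20 (SE over genes). Non-T cells diluting the pool are argued against as the whole cause, because genes of T cell identity differed by only -0.39 ± 0.20, which is 1.37 ± 0.28 above the Treg core genes. Other T cells in the pool are a candidate explanation: genes of naive cells and lymph node homing (7 of 19 in another list) were higher by 0.98 ± 0.30, though unevenly, with 6 of 19 lower (the abundant Il7r at 12.36 on that array and 13.11 and 12.83 on the others), and CD8 T and NK cell genes (3 of 14 in another list) by 1.93 ± 0.28, with Gzma at 12.20 on that array and 9.42 and 9.25 on the others. B cell genes were higher as well, by 3.97 ± 0.30, with Ms4a1 at 12.75 on that array and 8.28 and 7.66 on the others. High B cell genes did not always go with low Treg core genes. On iTreg replicate 1 the B cell list scored 1.82 and the Treg core list -0.048, against 2.78 and -1.43 on nTreg replicate 1. A gate on CD4, EGFP and Thy1.1 should remove B cells, NK cells, CD8 T cells and T cells without the Foxp3 reporter. The naive list was not restricted to genes absent from B cells, and the CD8 list includes NK cell genes. Their rise therefore cannot tell other T cells from B cell or NK cell RNA. The same array also had the highest poly-A spike-in and 18S signals of the 6, at 13.6 and 12.2, whose bearing on these genes was not tested. With 1 array, a true difference between pools of natural cells stays open and was not tested.

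Of the 10 genes given as lower in iTreg, C1qa, C1qb, Mrc1, Clec4n, Slc40a1, Hmox1 and Vcam1 are known from macrophages, which the gate on CD4, EGFP and Thy1.1 should remove. Macrophage RNA in the nTreg pools may account for this at numbers 1 and 2, where the median of 17 other macrophage genes was -0.94 ± 0.33 and -0.33 ± 0.10, with 13 and 15 of them lower in iTreg. Their list was chosen after the data were seen, and 6 of the 17 also stand in the myeloid list and 1 in the T cell lists. Abundant myeloid genes went both ways at numbers 1 and 2: Lyz2 (11.96 and 9.72 in nTreg, 10.40 and 8.90 in iTreg) and Csf1r (11.25 and 8.97, 9.49 and 8.28) read lower in iTreg, while Ctss (13.01 and 13.24, 13.22 and 13.30) read higher and Ctsb was level at number 1 (11.69 and 11.70). Ctss and Ctsb read high on every array, so a small amount of macrophage RNA would move them little, and they do not decide. The explanation stays open there too. At number 3 the median was -0.0036 ± 0.13, which does not decide, and a difference between the cells themselves stays open and was not tested.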

How the results depend on the processing

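No probe set or gene passed in limma under any alternative run, and Foxp3 kept its direction under each. Over all alternatives the lists gave 428 results on the same side of the threshold with the same direction, 41 newly past it, 64 no longer past it and 59 reversed. The named genes kept their direction without passing in 329 and reversed in 16. All of these reversals fell among the origin markers. The other named genes were chosen for their small p on the same arrays, so their kept direction is no support for them. Direction is camera's, relative to other genes, so some means below keep their sign; unless stated, the cause was not tested. The count of lists, 11, was 0 with the correlation estimated per list, 0 with fry, 0 with the replicate block and an estimated correlation, 17 with the replicate block, 4 with array weights, 6 without replicate 1 in both groups (chosen after seeing the data) and 7 to 20 with single arrays left out. The block changed the 6 list calls and the 4 list members given with it and no other call. Differences of at least 2-fold, 58, numbered 100 to 353 with single arrays left out, where fewer arrays enter the means. Of those under an unadjusted p of 0.05, 46.7% were higher in iTreg, 52.6% with quantile normalization, 37.7% with centring and 57.1% with array weights, over a range from 15.5% without iTreg replicate 3 to 67.4% without replicate 1 in both groups. Pseudocounts were not run, as the values were already log2. Dim probe sets such as that of Foxp3 limit what can be compared.

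With the mean of all probe sets of a gene, lists reversed for naive cells (-0.0084), cholesterol synthesis (0.00066) and recombination (0.0080). Recombination also reversed without a filter (0.034) and with the 60th percentile (0.033). With array weights the reversed values were -0.00083 for naive cells, -0.13 for oxidative phosphorylation, -0.12 for cholesterol synthesis, -0.11 for apoptosis, 0.20 for B cells, 0.21 for MHC class II, -0.013 for dendritic cells, 0.060 for stroma, 0.25 for sex-linked genes, -0.071 for Ikzf2, -0.19 for Nrp1, 0.15 for Swap70 and 0.21 for Igfbp4. Without replicate 1 in both groups they were -0.017 for origin markers, 0.12 for naive cells, 0.054 for Th1, 0.026 for Th17, 0.040 for Tfh, -0.018 for T cell receptor early response, -0.012 for IL-2, 0.089 for B cells, -0.072 for Ikzf2 and 0.20 for Dapl1.

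With single arrays left out, the lists and genes that reversed ranged as follows: Treg core from -0.081 to 0.91, origin markers from -0.18 to 0.22, naive cells from -0.33 to 0.28, Th1 from -0.20 to 0.14, interferon from -0.23 to 0.13, T cell receptor early response from -0.044 to 0.36, TGF-beta from 0.036 to 0.43, IL-2 from -0.024 to 0.58, oxidative phosphorylation from -0.14 to 0.24, cholesterol synthesis from -0.10 to 0.16, apoptosis from -0.10 to 0.19, coinhibitory receptors from -0.028 to 0.41, recombination from -0.019 to 0.12, B cells from -1.24 to 1.06, plasma cells from -0.24 to 0.37, MHC class II from -0.98 to 0.84, dendritic cells from -0.37 to 0.24, CD8 T and NK cells from -0.77 to 0.23, gamma delta T cells from -0.55 to 0.27, erythroid cells from -0.84 to 0.0053, platelets from -0.40 to -0.0069, stroma from -0.21 to 0.048 and T cell identity from 0.018 to 0.30. Among lists not reversed in camera's direction, glycolysis ranged from -0.035 to 0.13 and sex-linked genes from -0.98 to 0.086, which turned the sign of their means, Th17 from 0.066 to 0.23 and Tfh from 0.053 to 0.24. Ikzf2 ranged from -0.25 to 0.85, Nrp1 from -0.26 to 0.82, Swap70 from -0.37 to 0.32, Dapl1 from -1.11 to 0.71 and Igfbp4 from -0.81 to 0.75.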

Other observations

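All tests in this part were chosen after the results were seen. The replicate numbers marked pools that differed most in genes of B cells and antigen presentation. In the F test of the block 1128 of 27022 probe sets passed, with 8180 at an unadjusted p under 0.05. Of the B cell list 16 of 18 genes passed, and of the MHC class II list 9 of 9, against 3.07% of all genes. Ebf1, a transcription factor of B cells, averaged 9.79, 4.15 and 4.66 at numbers 1, 2 and 3, Ms4a1, the B cell antigen CD20, 12.4, 7.69 and 8.39, and the MHC class II gene H2-Aa 13.7, 9.95 and 10.5.

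Sex-linked genes differed between arrays, and the labels do not give the sex of the mice. Xist, transcribed from the inactive X chromosome, read 10.72, 12.87 and 7.18 on nTreg replicates 1, 2 and 3, and 12.69, 12.53 and 12.02 on the iTreg replicates. The Y-linked gene Eif2s3y read 10.19, 6.97 and 10.31 in nTreg and 7.83, 5.17 and 9.29 in iTreg, and Kdm5d 7.91, 4.05 and 7.66 in nTreg and 4.61, 3.03 and 6.83 in iTreg. The Y-linked gene Uty read 5.39, 4.94 and 6.42 in nTreg and 4.76, 5.29 and 5.95 in iTreg. Xist was thus higher in iTreg at numbers 1 and 3, Eif2s3y and Kdm5d were lower in iTreg at each number, and Uty was lower at numbers 1 and 3 and higher at number 2.

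The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. Probe sets past adjusted p 0.05 were 0 in the real split and at most 1 in any other, so that 10 of 10 splits gave as many, and the same held with at least 2-fold added. Genes past the threshold were 0 in the real split and at most 0 in the others, again 10 of 10. At least 2-fold differences numbered 58 in the real split and up to 1111 in another, with 8 splits giving as many, and lists past the threshold 11 and up to 18, with 6 splits giving as many. The split that put nTreg replicates 1 and 2 and iTreg replicate 2 on one side had 6159 probe sets under an unadjusted 0.05, against 45 in the real split. That split kept the arrays numbered 2 and those numbered 3 together but parted those numbered 1. Its count therefore does not single out the replicate number, and its cause was not tested. The real split is 1 of 4 that part every pair. Among these 4, the other 3 had 97 to 147 probe sets under an unadjusted 0.05, or 961 to 1760 with the replicate block against 390 in the real split. They had 5 to 9 lists against 11, and 52 to 106 differences of at least 2-fold against 58.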
